A study of Mus musculus with 6 samples.

How the data were processed

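RNA from splenic cDC2s of C57BL/6 mice was sequenced in 6 libraries, 3 from wild-type (WT) and 3 from Arhgef1 knockout cells, with the group and replicate number of each library taken from its title in the labels. Libraries were made from total RNA with standard Illumina protocols, per the labels; how the cells were sorted is not given in the sources used here. The deposited values were raw read counts per gene symbol, whole numbers with 1 column per library and no normalization, and the submitters' processing notes name STAR, HTSeq, DESeq2 and the genome build mm10. Versions of these tools, the annotation, the strand setting and the filter that left 14788 symbols are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and genes of families with near-identical copies (the H2, histone, Cd209 and Klra families) are uncertain, since the counting could split or drop their shared reads.

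Total counts per library ran from 8408325 to 11714365, and 121 genes had 0 counts in all 6 libraries. The 45S ribosomal RNA precursor Rn45s took 3.58% to 4.13% of the counts of a library. Malat1 took 3.66% to 4.43% in WT and 2.21% to 2.67% in the knockout. The source names in the labels put all WT libraries in lane 1 of a run name and all knockout libraries in lane 2 of a different run name. Lane, run name and genotype therefore cannot be told apart.

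Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 11504, library sizes were scaled by TMM (factors 0.977 to 1.02), and a quasi-likelihood model with genotype as its term was fitted to all 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher, lower or, in the text, risen or fallen in the knockout, with no fold threshold. The common biological coefficient of variation was 0.189. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values use the TMM-scaled library sizes. Gene positions came from GENCODE vM21, which is on the mm10 assembly, and matched 14549 symbols.

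Before the data were examined, 45 gene lists (pathways, cell type markers and families) were fixed, together with the tests and alternatives. Of their 1125 entries in the lists with members in the table, 23 were matched through older symbols and 50 had no match. Lists with at least 3 tested members, 42 in all, were tested with limma's camera 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 42 lists. Each test was repeated with an estimated correlation, in which case 0 lists were called, 7 had an unadjusted p under 0.05 and the lowest adjusted p was 0.176, and with fry, which called 11 lists, 10 of them also called by camera. A list of mitochondrially encoded genes had no member in the table, a plasma cell list had too few tested members, and sex-linked genes served only as a check of the libraries.

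Genes named in the text were chosen by a rule fixed before the data were examined. The rule took Arhgef1, then the 12 largest rises and 12 largest falls among called genes whose 3 knockout values all lay on one side of the 3 WT values, with an average log2 CPM of at least 3 and a symbol that is not a predicted-gene name. It further took up to 4 members with the smallest p in each list, and 8 genes of interest (Gna13, Cd97, Rhoa, Esam, Cd4, Clec4a4, Itgax and Ccr7). A gene named outside the rule is marked as such. Some genes the rule takes, and some of the lists, are not reported here.

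The procedure was tested on simulated counts drawn from the means, sizes and dispersions of these libraries, with 11343 genes tested and 50 genes changed at each of 4 fold sizes. It recovered 50% of genes raised 1.5-fold, 74% of those raised 2-fold, 100% of those raised 4-fold and 46% of those lowered to 0.667 of their level, with 5 false calls. A simulated list of 25 genes raised by 0.4 on the log2 scale was called, and 0 of 20 unchanged lists were. The simulation drew genes independently, so it does not test the effect of correlation between the genes of a list. Its changed genes and list members came only from genes with a mean above 5 CPM, so it does not cover genes with lower counts. It also changed fewer genes than were called in the data, and the adjusted p depends on the share of changed genes.

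Alternatives were DESeq2 size factors, total counts without TMM and upper-quartile factors in edgeR, no filter and a stricter filter on low counts (5 CPM in at least 3 libraries), the 50 most abundant genes left out, DESeq2 1.42.0 with its Wald test, limma-voom, the replicate number as a block, and leaving out each library in turn. A correction for GC content and transcript length and a fit without the macrophage genes were added after the data were seen.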

Results

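The series measured gene expression by RNA sequencing in type-2 conventional dendritic cells (cDC2s) from the spleens of C57BL/6 mice. The cDC2 is the dendritic cell subset that presents antigen mainly to CD4 T cells. Of the 6 libraries, 3 came from wild-type (WT) cells and 3 from cells lacking Arhgef1, a guanine nucleotide exchange factor that activates the small GTPase RhoA downstream of receptors coupled to the G proteins G12 and G13. The table held counts for 14788 gene symbols. Total counts were 10702215, 8724642 and 8546267 in WT replicates 1, 2 and 3, and 8408325, 9595782 and 11714365 in knockout replicates 1, 2 and 3. After the filter on low counts, 11504 genes were tested. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. All 3 WT libraries came from 1 sequencing lane and all 3 knockout libraries from another, under different run names, per the labels. No comparison within a lane or a run name could be made.

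The targeted gene was examined first, because it checks the labels. Arhgef1 (ENSMUSG00000040940.18, mm10 chromosome 7, positions 24902912 to 24926594, plus strand, protein coding) fell in the knockout to 45.5% of its WT level. Its normalised count was 284 ± 35.6 CPM in WT and 129 ± 14.8 CPM in the knockout (SD, n = 3 each), a log2 fold change of -1.13 ± 0.11 (SE; edgeR adjusted p = 6.96e-06). The counts were 3000, 2754 and 2088 in the WT libraries and 987, 1238 and 1694 in the knockout libraries, so that every knockout library lay below every WT library after normalisation. The labels do not say which part of the gene was deleted, and reads from outside a deleted part would still be counted.

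In the knockout 34 of 40 cell cycle genes and 14 of 24 cholesterol synthesis genes rose, and 14 of 17 macrophage markers and 9 of 16 MHC class II genes fell. Camera called all 4 lists with a preset correlation and 0 of them with an estimated one (adjusted p = 0.280 with an estimated correlation for cholesterol synthesis, and 0.176 for the other 3). With fry the adjusted p was 0.00686 for cell cycle, 0.00737 for MHC class II and 0.0302 for macrophage markers. Cholesterol synthesis was not called with fry (adjusted p = 0.0596). In total 586 genes were higher and 527 lower in the knockout, or 9.67% of those tested, and 140 of the higher and 119 of the lower genes changed at least 2-fold. Among the largest rises were Gria3, a glutamate receptor subunit (2.01 ± 0.38 on the log2 scale), the DNA helicase gene Pif1 (1.91 ± 0.30), the sterol synthesis genes Sqle (1.85 ± 0.25), Lss (1.54 ± 0.23) and Hmgcs1 (1.51 ± 0.18), the linker histone gene Hist1h1b (1.64 ± 0.24) and the mitotic genes Cdc25c (1.65 ± 0.36), Kif2c (1.56 ± 0.28) and Gtse1 (1.53 ± 0.33). The largest fall was that of Slc15a2, a peptide transporter, from 53.2 ± 9.02 to 2.87 ± 1.48 CPM (log2 fold change -4.24 ± 0.28, adjusted p = 5.32e-08). Among the next largest falls were those of the chemokine receptor gene Ccr3 (-2.87 ± 0.41), Klra17 of the Ly49 receptor family (-2.38 ± 0.23), the iron exporter gene Slc40a1 (-2.25 ± 0.31), Vcam1 (-1.93 ± 0.27), Axl (-1.91 ± 0.27), Cd5l (-1.89 ± 0.36), Mrc1 (-1.88 ± 0.29) and Hmox1 (-1.86 ± 0.22). Each error is an SE. Ifrd2 (1.82 ± 0.41), Mybl2 (1.54 ± 0.37), Fcna (-1.85 ± 0.48) and Mertk (-1.78 ± 0.40) also belonged to the 12 largest changes in their direction, but each lost its call when 1 library was left out. These were Ifrd2 without knockout replicate 3 (1.38), Mybl2 without WT replicate 3 (1.21) or knockout replicate 2 (1.37), Mertk without WT replicate 1 (-1.37), and Fcna without WT replicate 1 (-1.31), knockout replicate 2 (-1.44) or knockout replicate 3 (-1.71). In 3126 genes, 27.2% of those tested, the 3 knockout values did not overlap the 3 WT values, against 10% by chance. The counts of higher and lower genes dropped to 334 and 264 without WT replicate 1, to 310 and 315 without WT replicate 2, to 383 and 351 without WT replicate 3, and to 319 and 311 without knockout replicate 2.

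**Figure D1:**
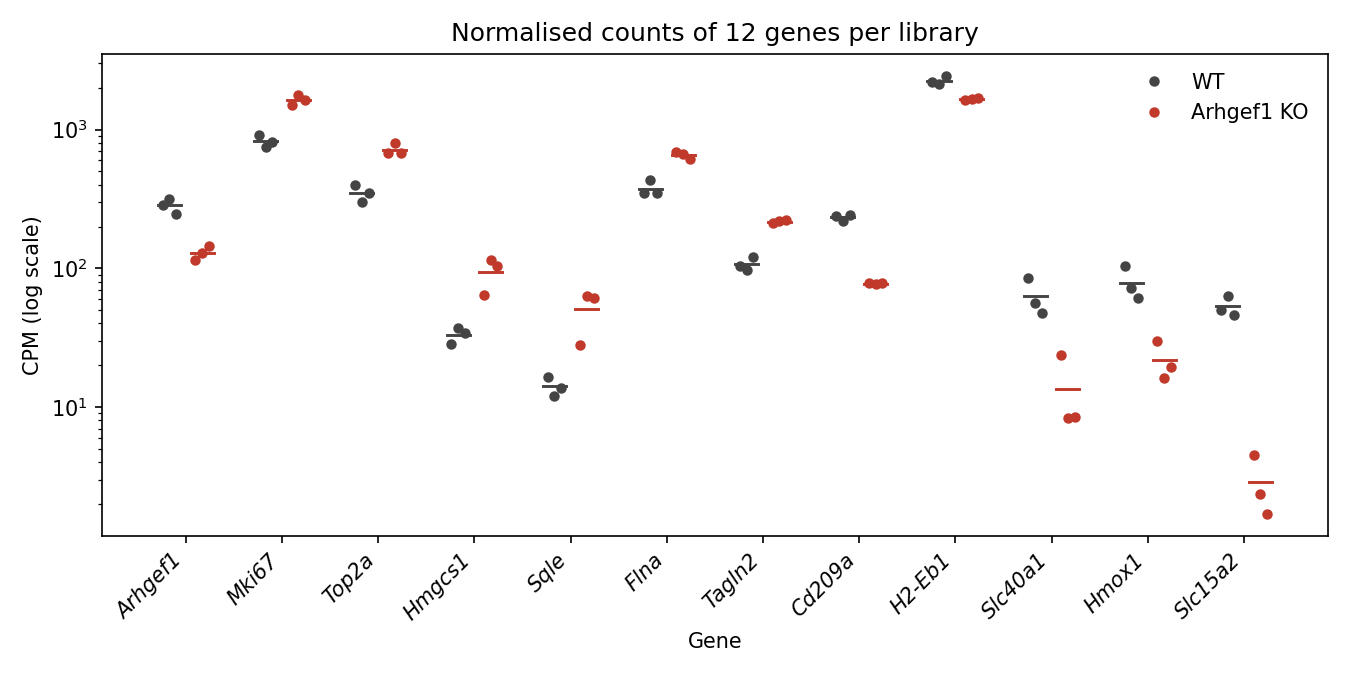
Normalised counts (CPM, log scale) of 12 genes in the 3 WT and 3 Arhgef1 knockout libraries, with each point a library and each line the group mean. Slc15a2 fell from a mean of 53.2 to 2.87 CPM and Mki67 rose from 823 to 1641 CPM.

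Cell cycle genes were about 2-fold higher in the knockout. Of 40 tested members, 34 rose and 6 did not pass the test, and 36 rose when adjusted over the list alone; the median log2 fold change was 0.98. Mki67, a marker of cycling cells, rose from 823 to 1641 CPM (adjusted p = 1.57e-06), Top2a, the topoisomerase of dividing cells, from 347 to 717 CPM (1.05 ± 0.10), and the mitotic motor genes Cenpe and Kif11 by 1.12 ± 0.11 and 1.10 ± 0.11. The list was called by camera with a preset correlation (adjusted p = 2.24e-58), and the call was lost with an estimated correlation (adjusted p = 0.176 with an estimated correlation). Replication-dependent histone genes had a median of 0.64, and 4 of 26 rose, 1 fell and 21 did not pass (5 and 1 adjusted over the list alone). Hist1h1b and Hist1h1e (0.95 ± 0.18) rose, as did H1f0 (0.70 ± 0.17), whose gene product is a replication-independent linker histone; Hist3h2a fell (-1.03 ± 0.17). For this list the adjusted p was 6.96e-04 with the preset correlation, 0.340 with an estimated correlation and 0.0787 with fry. H1f0 lost its call without WT replicate 2 (0.67) or knockout replicate 2 (0.48). Over the same libraries the macrophage list described further on fell, with a median of -1.73.

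In the cholesterol synthesis list 14 of 24 members rose and 10 did not pass (17 rose adjusted over the list alone), with a median log2 fold change of 1.07. Hmgcs1, which makes the precursor of mevalonate, rose from 33.2 to 94.3 CPM, and the squalene epoxidase gene Sqle from 14.1 to 50.6 CPM. The camera call (adjusted p = 9.45e-18) was lost with an estimated correlation (adjusted p = 0.280 with an estimated correlation) and with fry (adjusted p = 0.0596). The mean log2 CPM of the list was 3.52, 3.76 and 3.89 in WT replicates 1, 2 and 3, and 4.16, 4.92 and 4.89 in knockout replicates 1, 2 and 3. For the macrophage list the means were 5.18, 4.71 and 4.52, and 3.83, 2.92 and 2.83. In both lists knockout replicate 1 lay nearest to WT. Heat shock genes had a median of 0.45, and 6 of 12 rose (7 adjusted over the list alone), led by the chaperone genes Dnajb1 (0.87 ± 0.17), Hspd1 (0.68 ± 0.15), Hsp90aa1 (0.63 ± 0.14) and Hsph1 (1.10 ± 0.24). Without knockout replicate 2 the calls of Hspd1 (0.46), Hsp90aa1 (0.42) and Hsph1 (0.62) were lost. The adjusted p of the heat shock list was 6.78e-06 with the preset correlation, 0.340 with an estimated correlation and 0.181 with fry.

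Because Arhgef1 acts on RhoA, whose effect on actin controls the transcription factor pair MRTF and SRF, the cytoskeletal targets of MRTF-SRF were a comparison fixed before the data were examined. These genes were slightly higher in the knockout, with a median log2 fold change of 0.19, and did not move together: 8 of 21 rose, 2 fell and 11 did not pass (9 and 3 adjusted over the list alone). Tagln2, an actin-binding protein gene, rose from 107 to 217 CPM (1.02 ± 0.10), the filamin gene Flna from 376 to 654 CPM (0.80 ± 0.09) and Actb by 0.41 ± 0.06. The members that fell were Filip1l (-0.26 ± 0.06), whose call was lost without WT replicate 1 (-0.25), and the actin-bundling gene Lima1 (-1.03), named after its value was seen. The list was called with the preset correlation (adjusted p = 0.00118) and not with an estimated one (adjusted p = 0.280 with an estimated correlation). Genes of actin nucleation and dynamics had the same median, 0.19, and 12 of 43 rose (15 adjusted over the list alone), among them the cofilin gene Cfl1 (0.68 ± 0.10), the alpha-actinin gene Actn4 (0.59 ± 0.11), Coro1a (0.37 ± 0.07) and the Arp2/3 subunit gene Arpc1b (0.39 ± 0.08). Their camera adjusted p was 9.35e-05, and 0.340 with an estimated correlation. Rhoa itself stood at 183 ± 4.69 and 205 ± 17.3 CPM (0.16 ± 0.09, adjusted p = 0.339) and Gna13, which encodes a G protein that activates Arhgef1, at 240 and 273 CPM (0.19 ± 0.09, adjusted p = 0.248). Neither passed the test. The adhesion receptor gene Cd97 (Adgre5) had a log2 fold change of -0.03 ± 0.08 (adjusted p = 0.879). Over the same libraries the macrophage list fell, with a median of -1.73.

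Macrophage-associated genes were lower in the knockout by a median log2 fold change of -1.73. Of 17 members 14 fell and 3 did not pass (15 fell adjusted over the list alone). Vcam1 fell from 268 to 70.8 CPM, the F4/80 gene Emr1 (Adgre1) from 247 to 134 CPM (-0.88 ± 0.09), the heme oxygenase gene Hmox1 from 78.8 to 21.8 CPM, the transferrin gene Trf from 69.8 to 25.9 CPM (-1.42 ± 0.20) and Slc40a1 from 63.1 to 13.5 CPM. The whole list summed to 0.0846% to 0.130% of counts in the WT libraries and 0.0315% to 0.0476% in the knockout libraries. Its camera adjusted p was 9.91e-27, and 0.176 with an estimated correlation. Beside it, 7 of 22 Fc, C-type lectin and scavenger receptor genes fell (10 adjusted over the list alone) and the median was -0.32. The C-type lectin gene Cd209a fell from 234 to 77.6 CPM (-1.59 ± 0.10, adjusted p = 3.79e-08), the smallest adjusted p of any gene, and the adaptor gene Tyrobp fell by 0.49 on the log2 scale. The adjusted p of this list was 1.78e-08 with the preset and 0.176 with an estimated correlation. Genes of the ESAM-low, monocyte-related cDC2 subset had a median of -0.35. Of its 18 members 4 fell (6 adjusted over the list alone), among them Cd209a, the growth factor receptor gene Csf1r (-0.76 ± 0.16) and the lysozyme gene Lyz2 (-0.81 ± 0.21), of which Lyz2 lost its call without WT replicate 1 (-0.52), knockout replicate 2 (-0.85) or knockout replicate 3 (-0.56). The adjusted p was 3.57e-07, and 0.280 with an estimated correlation and 0.0596 with fry. In the monocyte list 3 of 15 fell (4 adjusted over the list alone), among them Csf1r and Plac8 (-0.43 ± 0.12), with a median of -0.12. Plac8 lost its call without WT replicate 1 (-0.40), WT replicate 3 (-0.38), knockout replicate 1 (-0.43) or knockout replicate 3 (-0.33). The camera call of the list (adjusted p = 0.0146, and 0.340 with an estimated correlation) was lost with fry (adjusted p = 0.0892) and without WT replicate 1 (median -0.14).

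In the MHC class II list 9 of 16 fell (10 adjusted over the list alone) and the median was -0.30, with H2-Eb1 going from 2255 to 1648 CPM (-0.45 ± 0.07), H2-Eb2 from 260 to 173 CPM (-0.59 ± 0.09) and the protease gene Ctss from 1115 to 813 CPM (-0.46 ± 0.07). The adjusted p was 5.82e-08, and 0.176 with an estimated correlation. In the conventional dendritic cell core list 6 of 17 fell (6 adjusted over the list alone; median -0.23), among them H2-Eb1, the peptidase gene Dpp4 (-0.42 ± 0.08), H2-Ab1 (-0.30 ± 0.06) and H2-Aa (-0.28 ± 0.06). Its adjusted p was 3.70e-04, and 0.218 with an estimated correlation. In the cDC2 identity list 5 of 22 fell (1 rose and 6 fell adjusted over the list alone; median -0.15): Cd209a, Cd4 from 515 ± 67.7 to 324 ± 64.2 CPM (-0.67 ± 0.12, adjusted p = 0.00138), Sirpa (-0.32 ± 0.07), Tnfaip3 (-0.42 ± 0.09) and Clec4a4 (-0.40 ± 0.11). Sirpa (-0.29) and Tnfaip3 (-0.39) lost their calls without WT replicate 1, and Clec4a4 lost its own without WT replicate 2 (-0.38), WT replicate 3 (-0.35), knockout replicate 1 (-0.39) or knockout replicate 3 (-0.34). The adjusted p of the list was 6.96e-04, and 0.176 with an estimated correlation. Esam (-0.35 ± 0.17, adjusted p = 0.232), the integrin gene Itgax (-0.16 ± 0.07, adjusted p = 0.204) and the migration receptor gene Ccr7 (-0.02 ± 0.16, adjusted p = 0.958) did not pass the test. Here too the macrophage list fell over the same libraries.

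Of 25 Toll-like receptor and signalling genes 5 fell (6 adjusted over the list alone; median -0.18), including Tlr7 (-0.78 ± 0.14), Tlr4 (-1.42 ± 0.27) and the trafficking factor gene Unc93b1 (-0.44 ± 0.08). The adjusted p was 4.20e-04, and 0.228 with an estimated correlation. Among 31 type I interferon response genes 7 fell (10 adjusted over the list alone; median -0.29). That list had an adjusted p of 1.48e-05 (0.490 with an estimated correlation and 0.257 with fry) and lost its call without WT replicate 1, when the median was -0.10. Of 25 immediate early genes 6 fell (2 rose and 9 fell adjusted over the list alone; median -0.21), among them Btg2 (-0.63 ± 0.09) and Dusp1 (-0.62 ± 0.10). The adjusted p was 0.00312 (0.340 with an estimated correlation and 0.135 with fry), and the call was lost without WT replicate 3 (median -0.13). In the dendritic cell maturation and migration list 1 of 33 rose and 7 fell (3 and 8 adjusted over the list alone; median -0.15), with H2-M2 at -1.47 ± 0.22, Ccl5 at -0.77 ± 0.16 and the costimulatory gene Cd86 at -0.57 ± 0.12. Its adjusted p was 0.0168 (0.476 with an estimated correlation and 0.212 with fry), and the call was lost without WT replicate 1 (median -0.11) or knockout replicate 2 (-0.06). The macrophage list was lower in the same knockout libraries as all of these groups.

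**Figure D2:**
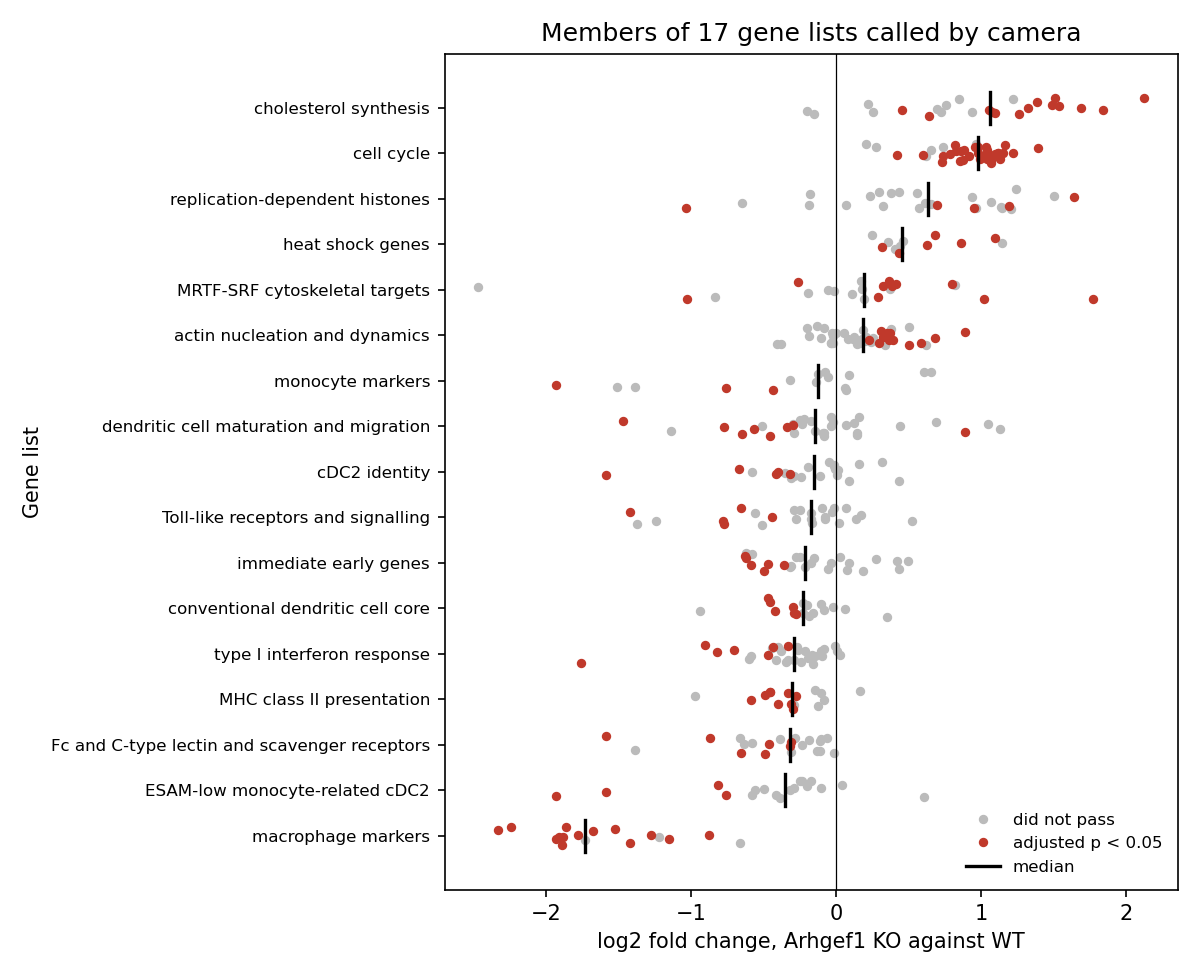
Log2 fold changes (knockout against WT) of the tested members of 17 gene lists called by camera with a preset correlation, with each point a gene, red where its edgeR adjusted p was under 0.05, and the black line the list median. Medians ran from -1.73 for macrophage markers to 1.07 for cholesterol synthesis; with an estimated correlation 0 of the 17 lists kept a call.

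The other 24 lists tested by camera were not called by it, though fry called the apoptosis regulators (fry adjusted p = 0.00686). With the preset correlation the genotypes gave 18 called lists. Another split of the 6 libraries, with both genotypes in each group, gave 21, but it kept part of the genotype difference. Markers of other cell types were mostly not past the test: of 12 B cell, 7 erythroid, 4 neutrophil, 3 platelet and 3 stromal or endothelial markers 0 passed the edgeR test, over all genes or adjusted over the list alone. In the T cell list Tcf7 rose (1 of 8; 1 adjusted over the list alone), in the NK cell list Klrk1 rose and Klrd1 and Ccl5 fell (1 and 2 of 6; 1 and 2 adjusted over the list alone), in the plasmacytoid list Spib and Pltp rose (2 of 12; 2 adjusted over the list alone) and in the cDC1 list Tlr11 and Cadm1 fell (2 of 17; 2 adjusted over the list alone). Tcf7, Pltp and Cadm1 each lost their call without WT replicate 1 (0.56, 0.68 and -0.80) and without other single libraries. The plasma cell list had too few tested members for camera, and Igj (0.97 ± 0.45) and Prdm1 (-0.62 ± 0.32) did not pass. Notch2-dependent ESAM-high cDC2 genes included 1 that rose and 3 that fell of 15 (1 and 4 adjusted over the list alone), MHC class I genes 0 and 2 of 16 (0 and 2), chemotactic receptors 1 and 1 of 18 (1 and 2) with Cxcr4 at 0.89 ± 0.12, integrins and adhesion molecules 2 and 3 of 33 (2 and 3), and NF-kB and inflammatory cytokine genes 1 and 4 of 23 (2 and 4) with Il1b going from 833 to 417 CPM. The figures in parentheses are again those adjusted over the list alone. Of 20 G12 and G13 proteins and coupled receptors 1 rose and 3 fell (1 and 6), of 6 YAP-TEAD targets 0 and 2 (0 and 2), of 27 apoptosis regulators 3 and 2 (4 and 2), of 17 glycolysis genes 2 and 0 (3 and 0), of 19 stress response genes 2 and 0 (3 and 0), of 74 oxidative phosphorylation genes 2 and 0 (1 and 0), of 76 ribosomal protein genes 1 and 4 (1 and 3), and of 27 neighbouring genes of Arhgef1 6 and 2 (7 and 2). Some of these lists were called when 1 library was left out: MHC class I without WT replicate 2 (median -0.20) or knockout replicate 2 (-0.21), YAP-TEAD targets without WT replicate 3 (-0.29), cDC1 markers without WT replicate 3 (-0.20) or knockout replicate 1 (-0.51), oxidative phosphorylation without WT replicate 3 (0.12) or knockout replicate 3 (0.13), ribosomal proteins without WT replicate 1 (-0.13), WT replicate 2 (-0.16) or knockout replicate 2 (-0.19), and stress response genes without WT replicate 3 (0.22) or knockout replicate 1 (0.26). In the NF-kB, Arhgef1 neighbour, erythroid and platelet lists the median, the mean and the test did not all have the same sign.

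Pearson correlations of log2 CPM across genes, which are not independent replicates, ran from 0.971 to 0.974 between WT libraries, 0.966 to 0.967 between knockout libraries and 0.954 to 0.965 between genotypes. On the first principal component of the 500 most variable genes, which held 36.9% of their variance, the WT libraries lay between -15.8 and -10.7 and the knockout libraries at 1.94, 19.0 and 19.5, with knockout replicate 1 nearer to WT replicate 2 than to either other knockout library. Counts differed between libraries of a genotype by more than sampling noise, with a chi-square per degree of freedom of 8.16 to 13.9. This does not tell separate animals from separate preparations of one sample. The macrophage list summed to its highest knockout value, 476 CPM, in knockout replicate 1, against 320 and 315 CPM in the other knockout libraries and 846 to 1299 CPM in WT. Xist made up 0.861% to 1.12% of counts in all libraries, and the Y-linked gene Ddx3y had at most 2 counts in any library.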

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

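The correction for GC content and length and the fit without macrophage genes were chosen after seeing the data. Under the 3 other scalings, both other filters, the 50 most abundant genes left out, DESeq2, limma-voom, the replicate block and the 2 added alternatives, the counts of higher and lower genes stayed within 1.5 times of 586 and 527; without TMM they were 692 and 431, and with upper-quartile factors 500 and 583. DESeq2 called 1362 genes, 1103 of them shared with the 1113 of edgeR in the same direction, and limma-voom called 1086 with 1037 shared. Leaving out each library in turn gave 310 to 583 higher and 264 to 489 lower genes, with 1 sample fewer in each fit, and 7 to 9 lists higher and 9 to 13 lower. Arhgef1 stayed past the threshold at -1.05 to -1.22, MRTF-SRF targets at 0.18 to 0.27, cell cycle at 0.91 to 1.04, cholesterol synthesis at 0.89 to 1.26 and macrophage markers at -1.42 to -2.14. With an estimated correlation camera called 0 lists higher and 0 lower, which includes the MRTF-SRF (median 0.19), macrophage (-1.73), cell cycle (0.98) and cholesterol (1.07) lists. In that order their correlations were estimated at 0.0701, 0.502, 0.262 and 0.568, against the preset 0.01. The cDC2 identity list also lost its call, at an estimated correlation of -0.0167. A correlation above the preset one is thus not the cause for that list, and the cause was not tested. With fry 6 lists were called lower, and 8 lists lost their call at adjusted p of 0.0596 to 0.257: cholesterol synthesis (1.07, adjusted p = 0.0596), heat shock, histone, ESAM-low, monocyte, interferon, immediate early and maturation; the cause was not tested. The other lists called by camera kept their call with fry, MRTF-SRF targets among them (fry adjusted p = 0.0302). Apoptosis regulators (median 0.07) were called with fry (adjusted p = 0.00686) but not with camera (adjusted p = 0.209). Among the named genes 181 of the repeated calls were lost, 20 gained and 2825 stayed on their side of the threshold, and no called gene or list changed direction. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.0382, -0.0326 and -0.0330. With the replicate block 945 genes were called, 914 of them shared. At this depth and spread, but with fewer genes changed than were called in the data, the simulation recovered 50% of 1.5-fold rises among genes above 5 CPM.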

Other observations

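The tests on the ESAM-low subset, Slc15a2, other lineages, GC content, sequencing lane, mixed wild-type cells and the chromosome segment around Arhgef1 were chosen after the results were seen; the splits of the samples and the correlation of macrophage genes were fixed before theirs.

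Of the 1113 changed genes 909 (81.7%) belonged to none of the fixed lists, against 10647 (92.6%) of the 11504 genes tested. Among the 20 changed genes outside the lists with the smallest p (a choice made after the values were seen) were E2f8 (1.31 ± 0.12 on the log2 scale, SE), Brca1 (1.22 ± 0.14), Neil3 (1.39 ± 0.15), Pole (1.09 ± 0.13), Kif4 (1.21 ± 0.13), Stil (1.10 ± 0.13) and the maintenance methyltransferase gene Dnmt1 (0.85 ± 0.10). Vim and Tubb5 rose, from 146 to 286 CPM and from 656 to 1136 CPM. The nuclear RNA Malat1 fell from 40494 to 24722 CPM, the ferritin gene Fth1 from 1245 to 731 CPM, the ion channel gene Trpm2 from 194 to 105 CPM, Lphn3 from 382 to 223 CPM and Neurl3 from 470 to 251 CPM.

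Of the 10 splits of the 6 libraries into groups of 3, the real split called 1113 genes, and the highest other split called 0 with edgeR, where the other splits had at most 511 genes at an unadjusted p under 0.05; 1 split, the real one, gave a count as large. For gene lists the real split gave 18 camera calls with the preset correlation. Another split gave 21 (WT replicates 1 and 3 with knockout replicate 1 against the rest), so that 2 splits gave as many. That split held more WT libraries in 1 group and more knockout libraries in the other, so it kept part of the genotype difference. A count of lists called this way therefore neither sets genotype apart nor shows that genotype does not matter. For the MRTF-SRF list the −log10 of the camera p was 3.38 in the real split and at most 2.70 in the others (1 split as large). With only 10 splits a share under 0.05 cannot be reached. The other splits put both genotypes in each group, so a genotype or lane difference became spread within groups and lowered their gene calls. The counts of 1113 and 0 therefore cannot decide what chance alone would give.

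The fall of macrophage genes may reflect fewer macrophages, or fragments of them, in the sorted knockout fraction. Within a genotype the deviations of the 17 members went together, with a mean pairwise correlation of 0.513 against 0.0851 at the 95th percentile of 10000 random lists matched on expression, which a shared source would give and a shared programme within cDC2s could give too; Vcam1 (268 CPM) and Emr1 (247 CPM) were the most abundant members in WT, 2 of the 17 (Axl and Marco) belong to another list, 12 still stood at 5 CPM or more in the knockout, and the gate that would remove such cells is not given. A lower share of ESAM-low cDC2s as the whole cause is argued against by the other members of that subset's list, whose median was -0.29 (SD 0.45) against -1.73. Slc15a2, at -4.24 ± 0.28, lay far under that median. This cannot decide whether loss of macrophages lowered Slc15a2, because the median need not equal that loss. Members that other sorted cells also express would fall less, and Emr1 (-0.88) still stood at 134 CPM in the knockout. An effect of the genotype within cDC2s is open and untested. With 0 lanes holding both genotypes, the sequencing lane and run name cannot be told apart from it.

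Cell cycle genes rose in the knockout, which may reflect more cycling cells in that fraction. The 42 tested markers of B, T, NK, plasma, neutrophil, erythroid and megakaryocyte cells summed to 14.2 CPM less in the knockout (-14.2 ± 55.8, SE). Mki67 rose by 819 CPM. The sum pools lineages whose members moved in opposite directions, with 2 markers past the test higher and 2 lower. Cd22 went from 364 to 404 CPM, without passing the test, and Klrd1 from 181 to 122 CPM. The sum therefore cannot decide whether cycling cells of a single such lineage were added. Trends with GC content and transcript length as the whole cause are argued against by the corrected median, 0.98 (SD of members 0.25). Cycling cells of the dendritic lineage, including precursors, also remain open and untested. The sequencing lane and run name cannot be told apart from genotype, since 0 lanes held both genotypes.

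Reads of Arhgef1 in the knockout at 45.6% of the fitted WT level could come from wild-type cells mixed into those samples. Against this, 16 genes outside the macrophage list had an upper 95% limit of their fold change below that of Arhgef1, with Slc15a2 at 5.28% of WT (upper limit 7.92%), lower than a mixture with that share of wild-type cells would allow if these cells keep their WT expression. Reads from parts of the gene that the allele leaves in place remain open and untested. A flanking chromosome segment from another strain stays open for the genes closest to Arhgef1. Of the 27 tested genes in the list of its neighbours, all within 0.858 Mb, 8 changed (29.6%), against 9.62% of other genes (odds ratio 3.95, 95% interval 1.49 to 9.49, two-sided Fisher's exact p = 0.00310). An effect of the allele on nearby genes would give this too and was not tested. Of the 8, 6 rose and 2 fell, among the latter Axl (-1.91), which also belongs to the macrophage list. The test was not repeated without Axl. Over 10 Mb to each side 23 of 213 genes changed (10.8%), against 9.73% elsewhere (odds ratio 1.12, upper 95% limit 1.75, two-sided Fisher's exact p = 0.561), a window that would dilute a shorter segment.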
